A study of Arabidopsis thaliana with 12 samples.

How the data were processed

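RNA was sequenced from Arabidopsis thaliana seedlings of the Columbia background, either wild type or carrying a mutation in the translation initiation factor eIF4E. The seedlings were 9 days old and were grown at 22 °C under 16 h of light and 8 h of darkness, and the labels place collection at zeitgeber time 16 h. From each genotype, total mRNA and mRNA bound to immunopurified ribosomes were each sequenced from 3 replicates with a stranded, poly(A)-selecting kit, which gave 12 libraries in 4 groups. The labels do not say whether the replicates came from separate cultures, so the p-values measure only the spread between these samples.

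The deposited tables list, for each gene of a library, the read counts as the authors made them, together with an FPKM value that the authors computed from the count, the gene length and the library's read total. Reads were aligned to the TAIR10 build with TopHat2 2.0.11, per the submitters' processing notes; the program that counted the reads is not given in the sources used here. Replicate libraries of a group differed by more than sampling noise (chi-square per degree of freedom of at least 7.07), and each counted as 1 replicate.

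The counts of listed genes per library ran from 21707431 to 22539336 in total wild type, from 17058704 to 19973299 in total mutant, from 18585324 to 24673644 in ribosome-bound wild type and from 20083555 to 22034288 in ribosome-bound mutant libraries. The listed genes held 95.7 to 97.9% of the read total behind the FPKM values. A tested gene had a median count of 337 to 479 in a library. A gene missing from a table was taken as 0 counts (3308 genes were missing from at least 1 table, and the highest count of such a gene elsewhere was 51). Gene symbols came from the RefSeq table of assembly TAIR10.1, which matched 25710 of the 25835 gene identifiers. Its chromosomes and start positions gave the order of neighbouring genes. Its gene spans served to find each library's read total behind the FPKM values, as the total that the largest number of genes gave. The gene lengths used below were computed back from the counts, the FPKM values and these totals. Of the tested genes, 8501 had a symbol. The tables held 0 identifiers of organelle-encoded genes, so the lists of chloroplast-encoded and mitochondrion-encoded genes had no tested member. Near-identical members of gene families, such as the LHCB1 and RBCS genes, and overlapping genes are uncertain where the counting could have split their reads.

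The tests, the gene lists, the rule for naming genes and most alternatives were chosen before the data were examined. The design assumed that only FPKM values would be present and foresaw edgeR's quasi-likelihood test for raw counts, which the tables turned out to hold, so edgeR was used. Genes with a mean FPKM of at least 1 over the 12 libraries were tested (19170 genes). Counts were scaled by TMM and fitted in edgeR 4.0.16 (R 4.3.3) with 1 mean per group, which left 8 residual degrees of freedom. The common dispersion was 0.0185 and the prior degrees of freedom 3.22. The contrasts tested were mutant against wild type in total mRNA, the same in ribosome-bound mRNA, the difference of these changes (the interaction), and ribosome-bound against total mRNA in each genotype. Tests were two-sided, with Benjamini-Hochberg adjustment within a contrast and a threshold of 0.05. Log2 changes are given with standard errors taken from the estimate and its F statistic, and FPKM levels with SDs over 3 libraries. EIF4E1 and its relatives were also compared by exact two-sided permutation tests of the mean FPKM, 3 libraries against 3, whose smallest possible p is 0.1.

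Gene lists covered the clock (morning-phased, evening-phased and post-translational regulators), flowering (promoters, repressors and the autonomous pathway), translation (cap-binding complex, eIF3 with eIF2 and TOR, cytosolic ribosomal proteins, and RPL18B, a ribosomal protein gene used for tagging ribosomes), photosynthesis (light harvesting, photosystem cores with Rubisco, light signalling), stress and hormones (salicylate, jasmonate, abscisic acid with cold and drought, heat shock, sugar starvation, auxin), genes with regulatory upstream reading frames, nutrition (iron, phosphate, and sulfur with glucosinolates), flavonoids, cell division, and markers of root, guard cells, phloem and shoot meristem. Lists with at least 3 tested members (27 of 31) were tested with camera in limma 3.58.1 at a preset correlation of 0.01 and adjusted over the lists of a contrast. Camera with an estimated correlation called 0 lists in each of the 5 contrasts. Fry, which tests whether the genes of a list move on balance 1 way without comparing them with other genes, called 12, 15, 1, 19 and 18 lists in the order of contrasts above, where camera with the preset correlation called 8, 13, 2, 4 and 6.

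Genes were named by rule: EIF4E1 and its cap-binding relatives; the 8 highest and 8 lowest log2 changes with a symbol among genes past the threshold, with non-overlapping groups and a mean of at least 5 FPKM in the higher group (for the interaction, overlap was not asked for); up to 4 members with the lowest p of each described list; and any member of the clock and flowering lists. CYP71A16, SCR and S6K2 were named outside this rule, after their values were seen. 1 gene picked by this rule is not reported here.

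The replicate numbers paired the libraries. Deviations from the group means correlated by 0.193 to 0.795 between libraries of the same number and by -0.727 to 0.271 between libraries of different numbers. On the third principal component, which held 10.2% of the variance, the 4 libraries of replicate 2 lay between -37.7 and -11.0 and the other 8 libraries between 3.01 and 23.4; the first component (61.7%) separated the kinds of library and the second (16.8%) the genotypes. The main design had no replicate term, and a fit with the replicate number as a block was run beside it.

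Alternatives included DESeq2 1.42.0, limma on log2(FPKM + 1) and with pseudocounts of 0.1 and 5, other filters and scalings, library weights, the replicate block, a fold minimum, leaving out each library or each replicate number, and a per-library correction for a smooth trend on gene length. DESeq2, limma with a pseudocount of 1, scaling by library size alone, leaving out a replicate number in all groups and the length correction were added after seeing the data. A named gene to which DESeq2 gave no adjusted p has no value under that setting.

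The procedure was tested on simulated data with known changes in 200 of 19170 genes. In the simulated total contrast edgeR recovered 50.7, 79.1 and 98.5% of genes changed by 1.5, 2 and 4-fold, in the ribosome-bound contrast 46.3, 76.1 and 97.0%, and in the interaction 16.4, 56.7 and 86.4%. False calls made up 5.59, 8.18 and 6.19% of its calls, and 18.8, 19.2 and 23.7% of those of DESeq2. Camera called the simulated list of 25 changed genes and 0 of 25 unchanged lists. Genes were drawn independently of each other, so the simulation cannot tell how the preset correlation fares for lists whose genes vary together.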

Results

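Seedlings of wild type and of an eif4e mutant of Arabidopsis were compared at 2 levels, the total mRNA and the mRNA attached to immunopurified ribosomes, with 3 replicates in each of the 4 groups. eIF4E is the protein that binds the cap of an mRNA at the start of translation. The series asks how the mutation alters both levels, with flowering and the circadian clock in its title. Each of the 12 libraries held between 17058704 and 24673644 counts, and 19170 genes were tested. Replicates of a group correlated by 0.976 to 0.993.

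EIF4E1 (AT4G18040), the gene to which the mutant's name refers, was lower in the mutant in both kinds of library. In total mRNA its level was 44.7 ± 0.986 FPKM (SD, n = 3) in wild type and 13.6 ± 9.18 FPKM in the mutant, a log2 change of -1.60 ± 0.33 (SE, adjusted p = 0.0083). The wild type libraries held 45.8, 44.0 and 44.2 FPKM and the mutant libraries 8.28, 24.2 and 8.29 FPKM, in the order of replicates. In ribosome-bound mRNA the level was 84.0 ± 10.9 FPKM in wild type (71.8, 92.9 and 87.2) and 12.6 ± 1.17 FPKM in the mutant (12.3, 11.6 and 13.9), a log2 change of -2.69 ± 0.33 (adjusted p = 9.3e-04). Groups did not overlap in either kind, and the exact permutation p was 0.1 for both, the smallest possible. Leaving out replicate 1 in all groups gave -1.33 in total mRNA (adjusted p = 0.155) and -2.77 on ribosomes (adjusted p = 0.0752), and leaving out replicate 3 gave -1.35 in total mRNA (adjusted p = 0.0971). Without total mutant 2 the change in total mRNA was -2.30.

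**Figure D1:**
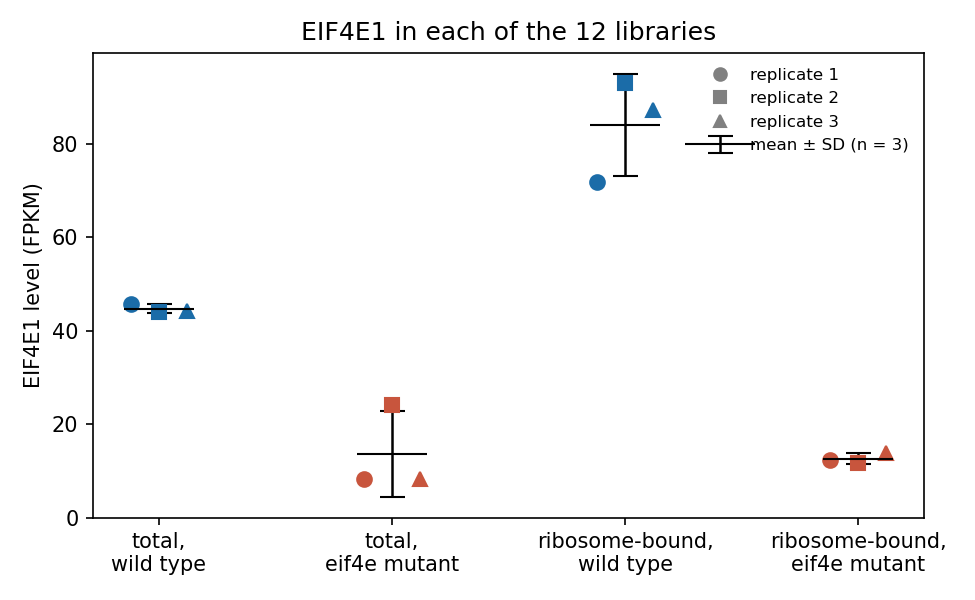
EIF4E1 level (FPKM, vertical axis) in each of the 12 libraries by group; symbols mark the replicate, and the horizontal line with bars is the mean ± SD of 3 libraries. The total mutant library of replicate 2 held 24.2 FPKM against 8.28 and 8.29 FPKM in the other mutant libraries of that kind.

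Other genes of the cap-binding complex moved little or rose. In total mRNA the poly(A)-binding protein genes PAB4 (0.74 ± 0.06 on the log2 scale, adjusted p = 4.5e-05) and PAB8 (0.51 ± 0.06), the cap-binding protein gene NCBP (0.62 ± 0.09), the helicase gene EIF4A1 (0.26 ± 0.06) and EIFISO4G2 (0.20 ± 0.06, adjusted p = 0.0485) rose. The isoform EIFISO4E (0.02 ± 0.07), its relatives eIF4E3 (-0.02 ± 0.18) and EIF4E1B (-0.12 ± 0.11) and the scaffold gene EIF4G (-0.20, adjusted p = 0.136) did not pass the test. Of the 15 listed members 5 rose and 1 fell, the same counts as adjusted over the list alone. The list did not pass (median 0.00, adjusted p = 0.152), and its median was negative under each of 3 other scalings. EIF4A1 lost its call without total wild type 1 or 3 or total mutant 2 or 3 (adjusted p up to 0.0727). EIFISO4G2 lost its call without any 1 library other than ribosome-bound wild type 2 (adjusted p up to 0.162).

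On ribosomes PAB8 (0.46 ± 0.06), EIFISO4G2 (0.33 ± 0.06), PAB4 (0.27 ± 0.06) and EIF4A1 (0.22 ± 0.06) rose and EIF4E1 fell, 4 up and 1 down of 15 (4 and 2 adjusted over the list alone). NCBP (0.21, adjusted p = 0.11), EIFISO4E (0.05), EIF4E1B (0.03), eIF4E3 (-0.24) and EIF4G (0.14, adjusted p = 0.268) did not pass. EIF4G turned with the length correction and then passed (-0.17, adjusted p = 0.0419, or 0.0165 with the block too). That list had a median of 0.15 and a mean of -0.05 (adjusted p = 0.218), and passed upward with quantile normalisation (0.0383) and no filter (0.0498). EIF4A1 lost its call without ribosome-bound wild type 1 or 3 or ribosome-bound mutant 1 (adjusted p up to 0.079). PAB4 (0.13, adjusted p = 0.117), EIF4A1 (0.14, adjusted p = 0.122) and EIFISO4G2 (0.16, adjusted p = 0.0633) did not pass on ribosomes with the length correction. PAB4 and EIFISO4G2 did with the block too.

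Photosynthesis and ribosomal protein genes rose in the total mRNA of the mutant. Of 21 tested light-harvesting genes 15 rose and 0 fell (17 adjusted over the list alone), with a median log2 change of 0.59. Among them were LHCB1.2 (1.24 ± 0.23), LHCB1.5 (1.23 ± 0.18), LHCB1.1 (1.22 ± 0.18) and LHCB5 (0.78 ± 0.14). Of 25 genes of the photosystem cores and Rubisco 17 rose (22 adjusted over the list alone, median 0.47), for example the Rubisco small subunit gene RBCS1A (0.79 ± 0.14), PSAE1 (0.68 ± 0.15) and PSAG (0.64 ± 0.11). Of 25 cytosolic ribosomal protein genes 20 rose (24 adjusted over the list alone, median 0.33), led by RPL7D (0.97 ± 0.08), RPS5A (0.59 ± 0.08) and RPS6B (0.57 ± 0.08). The lists passed with the preset correlation (adjusted p = 1.6e-12, 1.5e-11 and 2.4e-13), but each had adjusted p = 0.369 with an estimated correlation. By fry each moved up on balance (adjusted p = 0.0090, 0.0170 and 0.0028). Over 3 other scalings the medians of the photosystem and ribosomal protein lists fell as low as 0.12 and 0.18, and with quantile normalisation PSAE1 (adjusted p = 0.0619) and PSAG (0.0751) did not pass. RBCS1A was at 0.00 there, a value this method forces on a gene of the same rank in every library, so it decides nothing. In the same libraries root markers fell (median -0.53) and cell-division genes had a median of -0.47 (list adjusted p = 0.0702). RPL18B, outside that list, fell (-0.28 ± 0.07). It lost its call without total wild type 1, 2 or 3 or total mutant 1 or 3 (adjusted p up to 0.0783). If RPL18B carried the ribosome tag here, tag reads would enter its values.

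Genes of the iron-deficiency response rose in total mRNA while phosphate starvation genes fell, as did root markers (median -0.53). Of 13 iron-deficiency genes 6 rose and 1 fell (8 and 1 adjusted over the list alone, median 0.92), with an adjusted p = 5.5e-04 (adjusted p = 0.369 with an estimated correlation). IMA3, which encodes a small peptide of that response, went from 12.5 ± 3.71 to 33.7 ± 4.98 FPKM (1.56 ± 0.27), and the transporter gene OPT3 (0.88 ± 0.12) and BTS (0.38 ± 0.08) rose with it. The 1 member that fell was FER1 (-0.41 ± 0.06), whose product, ferritin, stores iron. Of 11 phosphate-starvation genes 0 rose and 5 fell (9 adjusted over the list alone, median -0.49), with an adjusted p = 9.6e-05 (adjusted p = 0.369 with an estimated correlation). PECP1 (-0.72 ± 0.15) and PPSPASE1 (-0.70 ± 0.19) were among them, as were MGD3 (-0.69 ± 0.15) and SQD2 (-0.49 ± 0.12), which make phosphorus-free membrane lipids. PPSPASE1 lost its call without total wild type 1 or 2 or total mutant 2 or 3 (adjusted p up to 0.114). SQD2 lost its call without total wild type 1 or total mutant 2 or 3 (adjusted p up to 0.0717).

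Root markers and auxin-response genes fell in total mRNA. Of 13 root markers 0 rose and 3 fell (1 and 5 adjusted over the list alone, median -0.53), with an adjusted p = 0.0012 (adjusted p = 0.367 with an estimated correlation). Those that fell were the beta-glucosidase gene BGLU22 (-1.13 ± 0.14) and the Casparian strip genes CASP2 (-0.59 ± 0.14) and CASP1 (-0.54 ± 0.09). Of 13 auxin genes 0 rose and 3 fell, as many adjusted over the list alone (median -0.21, or -0.32 at the lowest of 3 other scalings, adjusted p = 0.0054, but adjusted p = 0.367 with an estimated correlation). Among them were IAA19 (-0.90 ± 0.17) and GH3.5 (-0.70 ± 0.06). The auxin list did not pass with limma at each pseudocount (adjusted p from 0.0824 to 0.115). CASP2 lost its call without total wild type 1 or 2 or total mutant 1 (adjusted p up to 0.0644).

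The clock genes that passed in total mRNA rose. RVE1 (0.83 ± 0.22), RVE4 (0.57 ± 0.11) and LHY (0.46 ± 0.09) rose, 3 of 11 morning genes (3 adjusted over the list alone). That list missed the threshold (median 0.26, adjusted p = 0.0521, with the replicate block 0.0179, and adjusted p = 0.446 with an estimated correlation, or adjusted p = 0.29 with both). It passed without total wild type 1 or 3 or total mutant 2 or 3 (adjusted p down to 0.0138). It also passed with limma at each pseudocount (adjusted p from 0.0182 to 0.0205), each other scaling (0.0210 to 0.0461), no filter (0.0422), a filter of 5 FPKM (0.0407), the length correction (0.0279) and without replicate 2 or 3 in all groups (0.0249 and 0.0128). LWD1 (0.66 ± 0.09) and LWD2 (0.45 ± 0.13) rose among 6 post-translational clock regulators (4 adjusted over the list alone), whose list passed (median 0.27, or 0.16 at the lowest of 3 other scalings, adjusted p = 0.0204, but adjusted p = 0.369 with an estimated correlation). With a filter of 5 FPKM it did not pass (adjusted p = 0.0602). Of 12 evening genes LUX alone rose (0.25 ± 0.08, 0 adjusted over the list alone), and the list did not pass (median -0.07, adjusted p = 0.672). RVE1 lost its call without total wild type 1 or 2 or total mutant 1 or 3 (adjusted p up to 0.108). LWD2 lost its call without total wild type 1 or 2, total mutant 2 or 3 or ribosome-bound wild type 1 (adjusted p up to 0.154). LUX lost its call without any 1 library other than ribosome-bound mutant 1 or 2 (adjusted p up to 0.143). LWD2 (0.40, adjusted p = 0.0587) and LUX (0.22, adjusted p = 0.054) did not pass with the length correction, but both did with the block too.

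Among flowering genes CIB1 (0.90 ± 0.15), SPL3 (1.24 ± 0.32) and CDF1 (AT5G62430, 0.38 ± 0.10) rose and AGL24 (-0.72 ± 0.16) and the repressor FLC (-0.59 ± 0.18) fell in total mRNA. FT, which encodes florigen (-0.43 ± 0.20, adjusted p = 0.161), and SOC1 (-0.32, adjusted p = 0.217) did not pass. That made 2 up and 1 down of 14 promoters (the same counts adjusted over the list alone), 1 up and 1 down of 21 repressors (0 adjusted over the list alone) and 0 of 7 autonomous-pathway genes. Their lists had medians of -0.14, 0.05 and -0.00 and did not pass (adjusted p = 0.823, 0.836 and 0.764). SPL3 lost its call without total wild type 2 or 3 or total mutant 1 or 3 (adjusted p up to 0.0852). CDF1 lost its call without total wild type 1, 2 or 3 or total mutant 1 or 3 (adjusted p up to 0.104). AGL24 lost its call without total mutant 3 (adjusted p = 0.0528). FLC lost its call without any 1 library other than total wild type 3 or ribosome-bound mutant 2 (adjusted p up to 0.151). CDF1 did not pass with the length correction (0.33, adjusted p = 0.0566), but did with the replicate block too.

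Among the named genes with the largest changes in total mRNA were single genes of several kinds. The thionin gene THI2.2 (1.75 ± 0.38) and the salicylate markers PR1 (1.54 ± 0.41) and PR2 (6.13 ± 0.617 to 12.9 ± 3.49 FPKM) were among the 8 named genes with the highest changes, as was NDA1 (1.23 ± 0.10), a mitochondrial NADH dehydrogenase gene. JAZ8, a jasmonate repressor gene, went from 22.7 ± 11.6 to 3.67 ± 1.62 FPKM (-2.51 ± 0.72, adjusted p = 0.0351) and was the lowest. The next lowest were ddf2 (-2.32 ± 0.66), IDL1 (-1.97 ± 0.38), LTP4 (-1.84 ± 0.49), MRN1 (-1.77 ± 0.30), PROPEP4 (-1.75 ± 0.36), MSRB7 (-1.74 ± 0.45) and CYP705A12 (-1.73 ± 0.34). PR1 lost its call without total wild type 2 or 3 or total mutant 2 (adjusted p up to 0.0854). JAZ8 lost its call without total wild type 1 or 2 or total mutant 1, 2 or 3 (adjusted p up to 0.118). ddf2 lost its call without total wild type 1 or 2 or total mutant 1 or 3 (adjusted p up to 0.119). LTP4 lost its call without total wild type 2 or total mutant 1 or 3 (adjusted p up to 0.0996). MSRB7 lost its call without total wild type 1 or 2 or total mutant 2 or 3 (adjusted p up to 0.0845).

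The remaining lists did not pass in total mRNA. Of 16 genes of eIF3, eIF2 and TOR 6 rose and 1 fell (10 and 3 adjusted over the list alone, median 0.21, adjusted p = 0.0781, but 0.0150 with no filter, 0.0364 with library weights and 0.0408 with DESeq2). Of 32 light-signalling genes 3 rose and 1 fell (1 and 1 adjusted over the list alone, median 0.13). Of 19 salicylate genes 2 rose (2 adjusted over the list alone), with a median of -0.03 and a mean of -0.02 though the test pointed up, and down with the replicate block (adjusted p = 0.222). Of 15 jasmonate genes 2 rose and 1 fell (3 and 5 adjusted over the list alone, median -0.44, adjusted p = 0.713, but down at 0.0222 with the replicate block, where adjusted p = 0.163 with an estimated correlation). Both LOX2 (0.65 ± 0.09) and AOC2 (0.51 ± 0.10), which rose, encode enzymes of jasmonate synthesis. 1 gene fell of 22 for abscisic acid (1 adjusted over the list alone, median -0.12) and of 13 for sugar starvation (1 adjusted over the list alone, median 0.13). Of 19 genes with upstream reading frames 2 rose and 3 fell (2 and 4 adjusted over the list alone, median -0.05). Of 12 sulfur genes 3 fell (3 adjusted over the list alone, median -0.02), among them LSU1 (-0.78 ± 0.16). No member passed in edgeR's test, either way, among 6 heat-shock genes (median -0.21) and 17 flavonoid genes (median -0.10). More members passed with the replicate block. There 1 flavonoid gene rose and 7 fell, 5 salicylate genes rose and 6 fell, 2 jasmonate genes rose and 8 fell, and 5 abscisic acid and 1 heat-shock gene fell. Of light-signalling genes 8 rose and 1 fell with the block, of sugar-starvation genes 3 and 2, of upstream reading frame genes 2 and 7, of sulfur genes 3 and 3, of eIF3 genes 8 and 3, of evening genes 2 and 3, of repressors 2 and 2 and of morning genes 5 and 0. Falls numbered 9 for phosphate, 5 for auxin and 3 for cell division, and root markers had 1 up and 8 down.

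Of 5 cell-division genes 1 fell in total mRNA (3 adjusted over the list alone, median -0.47, adjusted p = 0.0702), of 4 phloem markers 1 fell (1 adjusted over the list alone, median -0.05) and of 7 guard cell markers TMM rose (0.63 ± 0.17, 1 adjusted over the list alone, median 0.27). The meristem gene STM, the 1 tested member of its list, rose (0.59 ± 0.12). With total mutant 2 left out, the lists of abscisic acid (adjusted p = 0.0472) and guard cell genes (0.0138) passed. That of cell division passed without total wild type 2 (0.0258), total mutant 3 (0.0117) or ribosome-bound mutant 2 (0.0158), without replicate 2 or 3 in all groups (0.0269 and 0.0309), with no filter (0.0422) and when only total libraries were fitted (0.0295). Other lists passed under few settings. They were guard cell, upward, without replicate 2 in all groups (0.0095) or with a pseudocount of 5 (0.0496), light signalling, upward, with no filter (0.0422), and downward abscisic acid with quantile normalisation (0.0163), jasmonate without replicate 3 (0.0205) and sulfur without replicate 1 (0.0378). With the block and length correction together cap-binding passed upward (0.0483, median -0.03), and abscisic acid and flavonoid downward (each 0.0439). With the length correction the lists of eIF3, eIF2 and TOR (adjusted p = 0.0276) and light signalling (0.0276) passed upward and that of cell division downward (0.042). TMM lost its call without total wild type 1, 2 or 3 or total mutant 1 or 3 (adjusted p up to 0.0957).

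In all, 3254 genes differed between the genotypes in total mRNA, 2001 higher and 1253 lower in the mutant (61.5% higher), of which 75 and 111 changed at least 2-fold. The share depended on scaling. It was 49.7% with median-ratio scaling (1583 higher, 1605 lower) and 25.2% with library size alone (1022 and 3034), where the median log2 change of all genes was -0.11. The values above are relative to a median of -0.0035. With the replicate block 6104 genes passed. Some named genes lost their call under other settings. EIF4A1, EIFISO4G2, LWD2, LUX and CDF1 did so with library size alone and with limma at each pseudocount, EIFISO4G2, LWD2, LUX and CDF1 with median-ratio scaling, EIF4A1, EIFISO4G2, LUX, FLC and AOC2 with quantile normalisation, EIFISO4G2 and FLC with DESeq2 or no filter, and EIFISO4G2 and LUX with a filter of 5 FPKM, no filter or no abundance trend. RVE1 and the guard cell gene TMM did so with a pseudocount of 0.1, TMM also with one of 1, JAZ8 with library weights or a robust fit, and EIFISO4G2 and ddf2 with a robust fit. When only the total libraries were fitted, EIFISO4G2, PR1, LWD2, LUX, FLC and TMM did not pass. Conversely EIF4G passed downward with library size alone, limma at each pseudocount and library weights, SOC1 with library weights, and FT with a pseudocount of 0.1 or the block with length correction. Leaving out 1 library gave 1662 genes without total wild type 2, 1673 without total wild type 1 and 1753 without total mutant 3. Leaving out replicate 1, 2 or 3 in all groups gave 473, 2008 and 801.

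Ribosome-bound mRNA showed changes in the photosynthesis, iron and phosphate lists and in light-signalling genes. Of 21 light-harvesting genes 9 rose (12 adjusted over the list alone, median 0.39), for example LHCB2.1 (0.76 ± 0.16) and LHCB6 (0.53 ± 0.14), with an adjusted p = 3.1e-05 (adjusted p = 0.414 with an estimated correlation). Of 25 photosystem and Rubisco genes 9 rose (13 adjusted over the list alone, median 0.32), for example RBCS3B (0.56 ± 0.15) and PSAD2 (0.53 ± 0.16), with an adjusted p = 1.9e-04 (adjusted p = 0.576 with an estimated correlation). Of 32 light-signalling genes 14 rose and 1 fell (16 and 1 adjusted over the list alone, median 0.27), with an adjusted p = 1.9e-04 (adjusted p = 0.33 with an estimated correlation). Among them were the photoreceptor genes PHYB (0.55 ± 0.09) and PHOT1 (0.53 ± 0.09) and SPA1 (0.40 ± 0.07). In the same libraries root markers (median -0.67) and cell-division genes (-0.60) were lower and guard cell markers (0.44) higher. LHCB6 lost its call without ribosome-bound wild type 2 (adjusted p = 0.0626). RBCS3B lost its call without ribosome-bound wild type 2 or ribosome-bound mutant 1 or 3 (adjusted p up to 0.0767). PSAD2 lost its call without ribosome-bound wild type 2 or ribosome-bound mutant 1 or 3 (adjusted p up to 0.101).

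Of 11 morning clock genes 5 rose on ribosomes and 0 fell, as many adjusted over the list alone (median 0.32, adjusted p = 0.0060, but adjusted p = 0.33 with an estimated correlation). RVE1 rose from 3.84 ± 0.918 to 8.39 ± 1.21 FPKM (1.19 ± 0.23), and CCA1 (0.79 ± 0.14), LNK2 (0.47 ± 0.14), RVE8 (0.45 ± 0.10) and LHY (0.34 ± 0.09) rose with it. Of 12 evening genes PRR5 rose (0.65 ± 0.15) and BOA (-0.48 ± 0.07), ELF4 (-0.41 ± 0.06) and GRP7 (-0.33 ± 0.10) fell (3 up and 4 down adjusted over the list alone, median -0.00, adjusted p = 0.607). The post-translational clock list did not pass (2 up of 6, 3 adjusted over the list alone, median 0.21, adjusted p = 0.0952), though it passed without ribosome-bound mutant 2 (0.0384), with no filter (0.0263) and with limma at each pseudocount (0.0407 to 0.0433). LHY lost its call without ribosome-bound wild type 2 or ribosome-bound mutant 2 (adjusted p up to 0.0811). LNK2 lost its call without ribosome-bound wild type 1 or 2 or ribosome-bound mutant 1 (adjusted p up to 0.12). GRP7 lost its call without ribosome-bound wild type 1 or 2 or ribosome-bound mutant 1 or 3 (adjusted p up to 0.101). After the length correction LHY (0.13, adjusted p = 0.342), LNK2 (0.29, adjusted p = 0.141), GRP7 (-0.18, adjusted p = 0.304) and ELF4 (-0.16, adjusted p = 0.0929) did not pass. ELF4 did with the replicate block too.

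FLC and FT both fell on ribosomes. FLC went from 7.69 ± 0.786 to 3.63 ± 0.447 FPKM (-1.04 ± 0.16, adjusted p = 0.0021) and FT fell to 4.17 ± 0.296 FPKM (-0.72 ± 0.18, adjusted p = 0.0146). AGL24 (-0.53 ± 0.15) also fell, CIB1 (0.82 ± 0.15) rose and SOC1 (-0.46 ± 0.17) missed the threshold (adjusted p = 0.0597, with the replicate block 0.0383). Of 14 promoters 1 rose and 3 fell (1 and 4 adjusted over the list alone, median -0.00, adjusted p = 0.888). Of 21 repressors 5 rose, among them CDF2 (0.47 ± 0.11), TEM1 (0.44 ± 0.15), SPA1 and COP1 (0.33 ± 0.07), and 2 fell (5 and 3 adjusted over the list alone). That list had a median of 0.05 and a mean of -0.02 (adjusted p = 0.744). The autonomous pathway, whose products keep FLC low, rose, 4 of 7 genes, as many adjusted over the list alone (median 0.26, adjusted p = 0.0088, but adjusted p = 0.33 with an estimated correlation). They were FLD (0.64 ± 0.11), FCA (0.33 ± 0.08), FPA (0.29 ± 0.06) and LD (0.26 ± 0.06). With the correction for gene length that list did not pass (adjusted p = 0.369), nor did FCA (0.04, adjusted p = 0.787), FPA (0.05, adjusted p = 0.676) and LD (0.05, adjusted p = 0.621). SPA1 (0.15, adjusted p = 0.0711), COP1 (0.20, adjusted p = 0.0596), TEM1 (0.44, adjusted p = 0.0562) and AGL24 (-0.46, adjusted p = 0.0609) did not pass either. These 4 genes did with the replicate block too. AGL24 lost its call without ribosome-bound wild type 2 or 3 or ribosome-bound mutant 2 or 3 (adjusted p up to 0.079). LD lost its call without ribosome-bound wild type 2 or ribosome-bound mutant 2 (adjusted p up to 0.0584). TEM1 lost its call without any 1 library other than total mutant 1 or 2 or ribosome-bound wild type 3 (adjusted p up to 0.144).

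Iron-deficiency genes rose on ribosomes too, 9 up and 1 down of 13 (10 and 1 adjusted over the list alone, median 0.75), with an adjusted p = 8.5e-04 (adjusted p = 0.33 with an estimated correlation). IMA3 (1.36 ± 0.25), OPT3 (0.75 ± 0.12) and BTS (0.69 ± 0.08) were up and FER1 (-0.43 ± 0.06) down. Of 11 phosphate-starvation genes 9 fell, as many adjusted over the list alone (median -0.41, adjusted p = 3.1e-05, but adjusted p = 0.33 with an estimated correlation), including IPS1 (-1.10 ± 0.19), SPX3 (-0.77 ± 0.16) and PAP17 (-0.28 ± 0.07). Of 12 sulfur genes 4 fell, as many adjusted over the list alone (median -0.22, or -0.14 at the highest of 3 other scalings, adjusted p = 0.0154, but adjusted p = 0.33 with an estimated correlation), including LSU1 (-1.10 ± 0.15) and GGCT2;1 (-0.98 ± 0.23). The sulfur list did not pass without ribosome-bound wild type 3 (median -0.09, adjusted p = 0.0752) or mutant 2 (median -0.13, adjusted p = 0.0563). Nor did it without replicate 3 in all groups (0.0589), with limma at each pseudocount (0.0519 to 0.0556), quantile normalisation (0.0664) or library weights (0.0656). PAP17 lost its call without ribosome-bound wild type 1 or 2 or ribosome-bound mutant 2 (adjusted p up to 0.0643).

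Markers of tissues and dividing cells also moved on ribosomes. Of 13 root markers 1 rose and 5 fell (1 and 8 adjusted over the list alone, median -0.67, or -0.31 at the highest of 3 other scalings), with an adjusted p = 1.9e-04 (adjusted p = 0.209 with an estimated correlation). BGLU22 (-1.57 ± 0.15), BGLU21 (-1.22 ± 0.25) and CASP1 (-0.67 ± 0.10) were among those that fell, and SCR, a regulator of root radial pattern, rose (0.30 ± 0.08). Of 13 auxin genes 4 fell, as many adjusted over the list alone (median -0.29, adjusted p = 0.0049, but adjusted p = 0.209 with an estimated correlation), among them IAA19 (-0.91 ± 0.16) and GH3.5 (-0.74 ± 0.06). Of 5 cell-division genes 4 fell (5 adjusted over the list alone, median -0.60, adjusted p = 0.0070, but adjusted p = 0.338 with an estimated correlation), for example CYCB1;1 (-0.60 ± 0.18) and CDKB2;1 (-0.59 ± 0.15). SCR lost its call without ribosome-bound wild type 1 or 2 (adjusted p up to 0.0677). CYCB1;1 lost its call without ribosome-bound wild type 1 or 3 or ribosome-bound mutant 1 or 2 (adjusted p up to 0.0858). SCR did not pass with the length correction (adjusted p = 0.171).

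Of 7 guard cell markers 3 rose on ribosomes, as many adjusted over the list alone (median 0.44, adjusted p = 0.0154, but adjusted p = 0.338 with an estimated correlation). They were TMM (1.06 ± 0.18), SPCH (0.72 ± 0.22) and FAMA (0.44 ± 0.11), regulators of stomatal development. The list did not pass without ribosome-bound wild type 3 (adjusted p = 0.0752) or replicate 3 in all groups (0.0814). SPCH lost its call without ribosome-bound wild type 2 or 3 or ribosome-bound mutant 1 or 3 (adjusted p up to 0.115). FAMA lost its call without ribosome-bound mutant 1 (adjusted p = 0.0535).

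Genes of eIF3, eIF2 and TOR rose on ribosomes, 7 up and 1 down of 16 (8 and 2 adjusted over the list alone, median 0.18), with an adjusted p = 0.0154 (adjusted p = 0.33 with an estimated correlation). EIF3A was at 0.54 ± 0.10 and EIF3E at 0.26 ± 0.06, and the 1 that fell was the kinase gene S6K2 (-1.06 ± 0.31). That list did not pass with the replicate block (adjusted p = 0.0691), without ribosome-bound mutant 2 (0.0809), without replicate 2 in all groups (0.147) or with the length correction (0.143). Ribosomal protein genes did not pass as a list (6 up of 25, as many adjusted over the list alone, median 0.07, adjusted p = 0.131), though they did without ribosome-bound mutant 1 (0.0059) or replicate 1 in all groups (0.0094). They also passed upward with the length correction (2.8e-05, median 0.19), quantile normalisation (0.0056), DESeq2 (0.041) and no filter (0.0204). RPL18B did not pass either (-0.15, adjusted p = 0.138). S6K2 lost its call without ribosome-bound wild type 1 or 2 or ribosome-bound mutant 2 or 3 (adjusted p up to 0.113).

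The named genes with the largest changes on ribosomes overlapped those of total mRNA. JAZ8 (-3.16 ± 0.70), the microRNA gene MIR397a (-3.05 ± 0.41), JAZ7 (-2.77 ± 0.67), EIF4E1, ddf2 (-2.64 ± 0.64), LTP4 (-2.56 ± 0.49), MSRB7 (-2.37 ± 0.51) and MIR399d (-2.31 ± 0.27) were the lowest 8. The highest 8 were PDF1.3 (1.81 ± 0.56), PR1 (1.73 ± 0.40), PR2 (1.34 ± 0.18), THI2.2 (1.23 ± 0.36), RVE1, the cytokinin response gene RR16 (1.17 ± 0.24), NDA1 (1.16 ± 0.10) and ARP9 (1.15 ± 0.07). PDF1.3 lost its call without ribosome-bound wild type 1 or 2 or ribosome-bound mutant 2 (adjusted p up to 0.143). THI2.2 lost its call without ribosome-bound wild type 2 or 3 or ribosome-bound mutant 2 (adjusted p up to 0.0953).

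LOX2 (0.90 ± 0.09) and AOC2 (0.48 ± 0.10) rose on ribosomes among 15 jasmonate genes, of which 2 rose and 3 fell (2 and 4 adjusted over the list alone, median -0.14, adjusted p = 0.871, but down at 0.0165 with the replicate block, where adjusted p = 0.174 with an estimated correlation, and at 0.0345 without replicate 3 in all groups). Of 19 salicylate genes 3 rose (3 adjusted over the list alone), with a median of -0.05 and a mean of -0.11 though the test pointed up, and down with the replicate block (adjusted p = 0.0691, or 0.0319 with length correction too). 1 of 22 abscisic acid genes fell (0 adjusted over the list alone, median -0.04) and 0 of 6 heat-shock genes passed (0 adjusted over the list alone, median 0.09, mean -0.10). Of 13 sugar-starvation genes 3 rose (0 adjusted over the list alone, median 0.16). Of 19 genes with upstream reading frames 4 rose and 3 fell (4 and 3 adjusted over the list alone, median -0.10). Of 17 flavonoid genes 2 fell (1 adjusted over the list alone, median -0.33), and of 4 phloem markers 0 passed (median -0.02). STM was at -0.18 and did not pass. The list of upstream reading frames passed downward with the length correction (adjusted p = 0.0246). In the fit with the replicate block 21 photosystem and 16 light-harvesting genes rose, 8 ribosomal protein genes rose and 2 fell, 3 salicylate genes rose and 8 fell, 3 jasmonate genes rose and 6 fell, and 8 flavonoid, 7 sulfur and 4 abscisic acid genes fell. Evening genes had 3 up and 4 down there, sugar-starvation genes 6 and 1, upstream reading frame genes 4 and 7, root markers 1 and 9 and heat-shock genes 0 and 1.

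In all, 5236 genes differed between the genotypes on ribosomes, 2943 higher and 2293 lower in the mutant (56.2% higher, and 44.2% with library size alone, 2118 and 2673), of which 46 and 364 changed at least 2-fold. With the replicate block 7914 genes passed. Of the named genes PDF1.3, LHY, LNK2, TEM1 and LD did not pass with limma at each pseudocount, FCA with pseudocounts of 1 and 5 and SPCH with one of 5, TEM1 and LD with library size alone, GRP7, PAP17 and CYCB1;1 with quantile normalisation, JAZ7 and JAZ8 with library weights and GRP7 with no filter. When only ribosome-bound libraries were fitted, PAB4, EIF4A1, PDF1.3, LHY, LNK2, PRR5, GRP7, TEM1, FCA, LD, LHCB6, PSAD2, PAP17, CDKB2;1, FAMA, SPCH, EIF3E and SCR did not pass. Conversely SOC1 passed with DESeq2 or library weights, RPL18B with DESeq2, and NCBP with quantile normalisation or the block with length correction. Fewer passed without ribosome-bound wild type 1 (3295) or 2 (3138) or ribosome-bound mutant 1 (3085), without replicate 2 in all groups (2940) and with the length correction (3472). Without replicate 1 in all groups 11 genes passed.

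**Figure D2:**
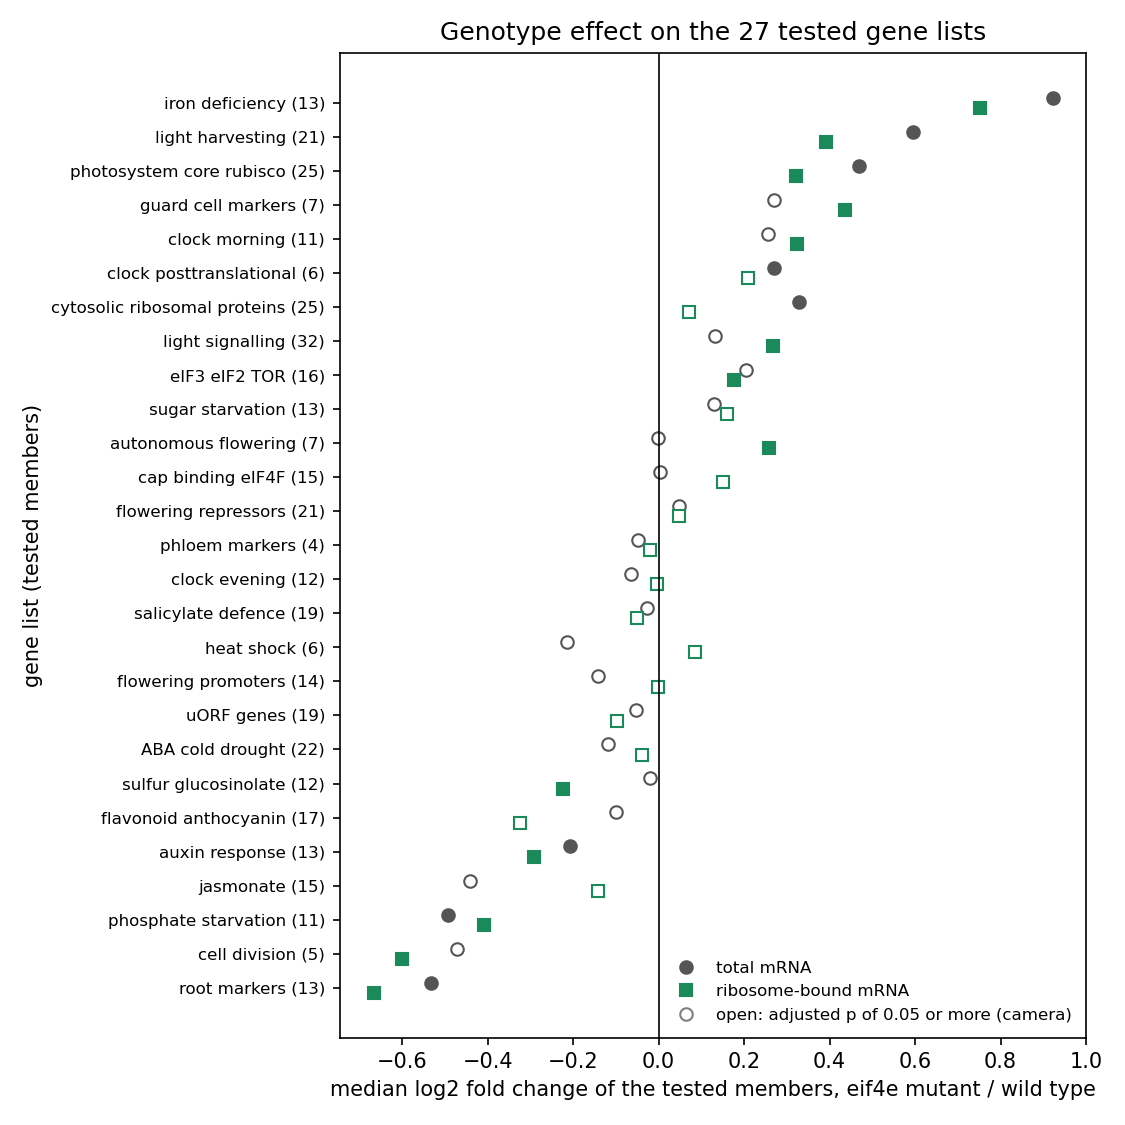
Median log2 change between mutant and wild type (horizontal axis) of the tested members of each of 27 gene lists (vertical axis, number of tested members in brackets), in total mRNA (circles) and ribosome-bound mRNA (squares); filled symbols have an adjusted p under 0.05 by camera with a preset correlation. Iron-deficiency genes lie at 0.92 and 0.75 and root markers at -0.53 and -0.67.

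Across 19170 genes, which are not independent replicates, the changes in both kinds of library had a Pearson r of 0.692 and a Spearman rho of 0.570. Total and ribosome-bound libraries of the same number and genotype shared deviations from their group means (correlations of 0.357 to 0.795), and other splits of the samples gave a Pearson r of 0.52 to 0.83. Independence is thus not the value without an effect. In both kinds 923 genes rose, where independent lists would share 307, and 609 fell, where they would share 150. Opposite calls numbered 110. Of all tested genes 69.1% changed with the same sign, and of the genes called in total mRNA 81.7%. With no filter on low genes r was 0.317.

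The interaction asks whether a gene's share on ribosomes, relative to its total mRNA, differed between the genotypes. Ribosomal protein genes lost ribosome association in the mutant, 0 up and 6 down of 25 (11 down adjusted over the list alone, median -0.23), with an adjusted p = 1.3e-07 (adjusted p = 0.996 with an estimated correlation). Among them were RPL7D (-0.74 ± 0.12), RPS5A (-0.54 ± 0.11), RPL23AA (-0.48 ± 0.10) and RPL27AC (-0.46 ± 0.10). With quantile normalisation that list did not pass (median -0.05, adjusted p = 0.384). Autonomous-pathway flowering genes gained association, 2 of 7 (3 adjusted over the list alone, median 0.29), with an adjusted p = 0.0031 (adjusted p = 0.658 with an estimated correlation). FLD (0.64 ± 0.16) and FCA (0.49 ± 0.10) passed and LD was at 0.29 (adjusted p = 0.0956). With the length correction that list did not pass (adjusted p = 0.60), nor did FLD (0.44, adjusted p = 0.264) and FCA (0.05, adjusted p = 0.968). RPS5A (-0.40, adjusted p = 0.0914) and RPL27AC (-0.18, adjusted p = 0.475) did not pass either, though RPS5A did with the block too. With the replicate block 11 ribosomal protein and 5 light-harvesting genes fell and 4 light-signalling genes rose. FLC (-0.45 ± 0.24, adjusted p = 0.331), FT (-0.29 ± 0.27, adjusted p = 0.635) and EIF4E1 (-1.09 ± 0.45, adjusted p = 0.207) did not pass. RPS5A lost its call without total wild type 1, 2 or 3, total mutant 2 or 3, ribosome-bound wild type 1 or ribosome-bound mutant 1 (adjusted p up to 0.0773). RPL23AA lost its call without any 1 library other than total mutant 1, ribosome-bound wild type 2 or 3 or ribosome-bound mutant 3 (adjusted p up to 0.0811). RPL27AC lost its call without any 1 library other than total mutant 1, ribosome-bound wild type 2 or 3 or ribosome-bound mutant 3 (adjusted p up to 0.0914). FLD lost its call without any 1 library other than ribosome-bound wild type 3 or ribosome-bound mutant 3 (adjusted p up to 0.12). FCA lost its call without any 1 library other than ribosome-bound wild type 3 or ribosome-bound mutant 2 or 3 (adjusted p up to 0.082).

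TCTP, UBC8, UBC28, ARFA1E, ZEU1 and AGL26 rose in total mRNA (log2 changes from 0.85 to 1.11) and did not rise on ribosomes (from -0.33 to 0.06). TCTP, which encodes the translationally controlled tumour protein, stood at 1751 ± 105 FPKM in total wild type and 3364 ± 313 FPKM in total mutant, against 1398 ± 133 and 1341 ± 87.5 FPKM on ribosomes (-1.09 ± 0.14). The ubiquitin-conjugating enzyme genes UBC8 (-1.14 ± 0.13) and UBC28 (-1.05 ± 0.13), AGL26 (-1.19 ± 0.09, adjusted p = 4.9e-04), ARFA1E (-1.06 ± 0.13), ZEU1 (-1.06 ± 0.15), SP1L2 and MIR399d (-1.93 ± 0.37) made up the lowest 8 with it. SP1L2 fell on ribosomes, from 15.7 ± 1.51 to 7.37 ± 0.394 FPKM, against 5.74 and 5.88 FPKM in total mRNA, and MIR399d was at -0.38 in total mRNA (adjusted p = 0.343). The highest 8 were TNO1 (0.76 ± 0.17), ATRX (0.74 ± 0.13), LIG6 (0.73 ± 0.17), PWD (AT5G26570, 0.71 ± 0.12), emb2458 (0.69 ± 0.13), SAB (0.69 ± 0.11), WRKY19 (0.68 ± 0.15) and MEE44 (0.68 ± 0.14). None of these highest 8 passed with the length correction (adjusted p from 0.0829 for PWD to 0.78 for SAB), nor did SP1L2 (0.0872) and MIR399d (0.0642). The changes were then from 0.10 (SAB) to 0.37 (PWD) for these 8, -0.89 for SP1L2 and -1.75 for MIR399d. PWD and MIR399d passed with the replicate block and length correction together. MIR399d lost its call without total wild type 1 or 3, total mutant 2, ribosome-bound wild type 1 or ribosome-bound mutant 2 (adjusted p up to 0.0669). TNO1 lost its call without any 1 library other than total mutant 1, ribosome-bound wild type 3 or ribosome-bound mutant 3 (adjusted p up to 0.101). ATRX lost its call without total wild type 1 or 2, total mutant 3 or ribosome-bound mutant 1 (adjusted p up to 0.0607). LIG6 lost its call without any 1 library other than total mutant 1, ribosome-bound wild type 3 or ribosome-bound mutant 3 (adjusted p up to 0.103). PWD lost its call without total mutant 3 (adjusted p = 0.0542). emb2458 lost its call without total wild type 1 or 2, total mutant 3, ribosome-bound wild type 1 or ribosome-bound mutant 1 or 2 (adjusted p up to 0.0679). WRKY19 lost its call without any 1 library other than total mutant 1, ribosome-bound wild type 3 or ribosome-bound mutant 3 (adjusted p up to 0.0912). MEE44 lost its call without any 1 library other than total mutant 1, ribosome-bound wild type 3 or ribosome-bound mutant 3 (adjusted p up to 0.0755).

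The kinase gene TOR (0.63 ± 0.10) and PHYB (0.52 ± 0.13) also gained association, and PAB4 (-0.47 ± 0.08), EIF3K (-0.47 ± 0.09), ELF4 (-0.40 ± 0.09) and STM (-0.76 ± 0.17) lost it. PHYB lost its call without any 1 library other than ribosome-bound wild type 3 or ribosome-bound mutant 3 (adjusted p up to 0.124). PAB4 lost its call without total wild type 1 or total mutant 3 (adjusted p up to 0.064). EIF3K lost its call without total wild type 1 or 2, total mutant 2 or 3, ribosome-bound wild type 1 or ribosome-bound mutant 1 or 2 (adjusted p up to 0.0751). ELF4 lost its call without any 1 library other than ribosome-bound wild type 3 or ribosome-bound mutant 3 (adjusted p up to 0.102). STM lost its call without any 1 library other than total wild type 3, ribosome-bound wild type 3 or ribosome-bound mutant 3 (adjusted p up to 0.0992). Corrected for length, TOR (0.06, adjusted p = 0.896), PHYB (0.17, adjusted p = 0.521), EIF3K (-0.31, adjusted p = 0.149) and ELF4 (-0.07, adjusted p = 0.911) did not pass. STM did not pass either (-0.72, adjusted p = 0.116) and PAB4 did (-0.62, adjusted p = 0.0067).

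The interaction followed gene length. In 5 equal groups of the tested genes by length the median log2 interaction went from -0.28 in the shortest (median 712 bp) to 0.23 in the longest (2836 bp). The genotype change went from 0.03 to -0.06 in total mRNA and from -0.25 to 0.19 on ribosomes. Across genes, which are not independent replicates, Spearman's rho between length and change was 0.629 for the interaction, 0.435 on ribosomes and -0.109 in total mRNA. Genes that gained association had a median length of 3729 bp and genes that lost it 858 bp.

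**Figure D3:**
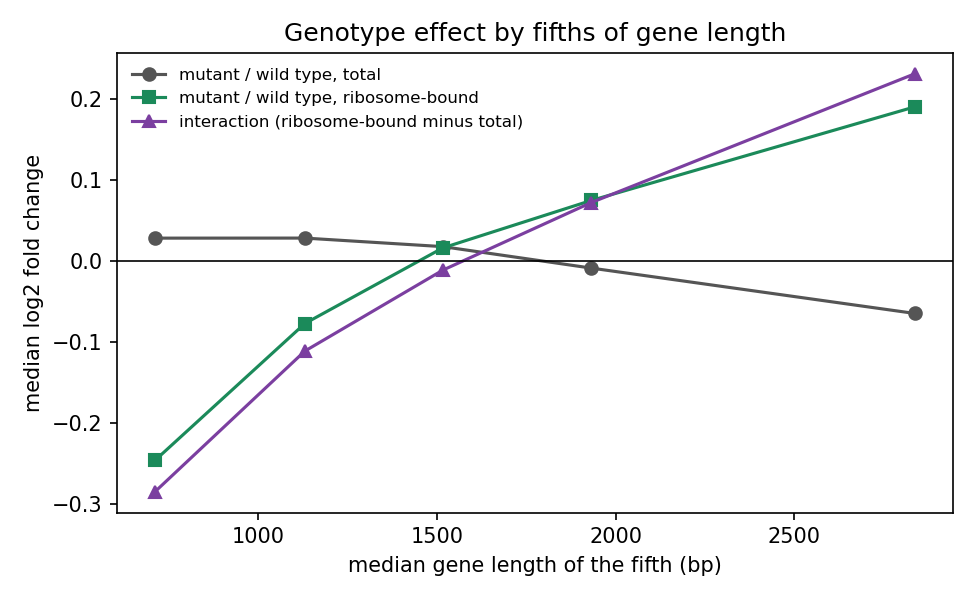
Median log2 change of the tested genes in 5 equal groups by gene length (horizontal axis, median length of the group in bp; vertical axis, log2 change) for the genotype effect in total mRNA (circles), on ribosomes (squares) and for the interaction (triangles). The interaction went from -0.28 in the shortest group to 0.23 in the longest, against 0.03 and -0.06 in total mRNA.

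In all, 772 genes passed for the interaction, 321 gained and 451 lost association, 1 and 40 at least 2-fold. Gains were 41.6% (63.6% with library size alone, 566 and 324). With the replicate block 1937 genes passed, as did the lists of light harvesting (adjusted p = 0.0070), photosystem and Rubisco (0.0043) and sulfur genes (0.0341) downward and light signalling (0.0305) upward, each with adjusted p = 0.863 with an estimated correlation. With quantile normalisation the light-harvesting and photosystem medians were positive (0.06 and 0.09). With a block for each genotype and replicate 4417 genes passed, and EIF4E1 with them (-1.01, adjusted p = 0.0086). After the length correction 134 genes passed (391 with the block). Under quantile normalisation PAB4, WRKY19, LIG6, TNO1, RPS5A, RPL23AA, RPL27AC, FLD, FCA, ELF4, EIF3K and PHYB did not pass, with limma on log2(FPKM + 1) RPL23AA, RPL27AC, EIF3K and STM, with a pseudocount of 0.1 these, LIG6 and RPS5A, and with one of 5 RPL27AC. LIG6, RPL27AC, FLD, ELF4, PHYB and STM did not pass with no filter, RPL27AC and STM with library size alone, nor FLD and PHYB with no abundance trend, while FLC passed downward with a pseudocount of 5 and LD upward with a block for each genotype and replicate. Counts without 1 library were 196, 191 and 260 (total wild type 1, 2 and 3), 235 and 159 (total mutant 2 and 3), 217 and 371 (ribosome-bound wild type 1 and 2) and 200, 297 and 1606 (ribosome-bound mutant 1, 2 and 3). Without replicate 3 in all groups 87 passed. Without replicate 1 or 2 edgeR called 0 (1932 and 2502 at an unadjusted p under 0.05), or 211 without replicate 2 with the block. With all replicates DESeq2 called 1352.

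Lists also passed for the interaction without single libraries. Light harvesting passed without total wild type 1 or 3, total mutant 2, ribosome-bound wild type 2 or ribosome-bound mutant 3 (adjusted p down to 0.0013). Photosystem and Rubisco genes passed without those or ribosome-bound mutant 1 (down to 7.3e-04), light signalling without total wild type 2, total mutant 1, ribosome-bound wild type 3 or ribosome-bound mutant 3 (down to 0.0171), and sulfur without ribosome-bound mutant 1 (0.0436). Photosystem and light-signalling lists each passed with library weights (0.0119), no filter (0.0235), a pseudocount of 0.1 (0.0407) and library size alone (0.0456), light signalling also with DESeq2 (0.0354) and light harvesting with library weights (0.0343). Without replicate 3 in all groups these 3 lists passed, and without replicate 2 both photosynthesis lists. With the block and length correction together the lists of sulfur and upstream reading frames passed downward (each 0.0190) and abscisic acid upward (0.0287).

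Ribosome-bound and total mRNA differed widely within each genotype, but uneven tissue recovery was not told apart from association. In wild type the cell wall protein genes EXT12 (-3.47 ± 0.40), EXT10 (-3.39 ± 0.54), HRGP1 (-3.22 ± 0.45), LRX1 (-3.12 ± 0.36), EXT6 (-3.11 ± 0.48) and PRP3, the starch-phosphorylating enzyme gene PWD (AT5G26570, -3.01 ± 0.09) and GH9C1 (-2.86 ± 0.42) were the most depleted of the named genes on ribosomes. The most enriched were CLE22 (2.86 ± 0.43), RL3 (2.51 ± 0.24), the metallothionein genes MT3 (2.50 ± 0.09) and MT2B, PDF2.1 (2.41 ± 0.19), SP1L5 (2.31 ± 0.24), TRX1 (2.23 ± 0.20) and RL4 (2.23 ± 0.26). In the mutant EXT12 (-3.87 ± 0.43), EXT6 (-3.87 ± 0.53), PRP1 (-3.72 ± 0.49), HRGP1 (-3.71 ± 0.48), PRP3 (-3.70 ± 0.50), EXT10 (-3.67 ± 0.57), LRX1 (-3.59 ± 0.40) and EXT13 (-3.56 ± 0.49) were the most depleted. MT3 (2.13), RPL18B (2.07), NAC097 (1.99), SP1L5 (1.96), TRX1 (1.96), RTFL14 (1.91 ± 0.39), MT2B (1.83 ± 0.10) and RL4 (1.81) were the most enriched there. RPL18B was enriched by 1.93 ± 0.07 in wild type.

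Of the cap-binding genes EIFISO4E was enriched on ribosomes by 0.94 ± 0.07 in wild type and 0.97 in the mutant and PAB2 was depleted (-0.82 ± 0.05 and -0.90). EIF4G was depleted too (-1.13 ± 0.09 and -0.79 ± 0.09), but turned to 0.31 and 0.19 with the length correction. EIF4E1 was enriched in wild type (1.03 ± 0.31, adjusted p = 0.0106), a call that ended with the length correction (0.38, adjusted p = 0.338) and without replicate 1 (0.0511) or 3 (0.0612) in all groups. In the mutant it was at -0.06 ± 0.34, and was enriched without total mutant 2 (0.64, adjusted p = 0.0023).

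Photosystem and Rubisco genes were enriched on ribosomes in both genotypes, 23 of 25 in wild type (23 adjusted over the list alone, median 0.79, adjusted p = 1.2e-04, but adjusted p = 0.761 with an estimated correlation). In the mutant 22 were (23 adjusted over the list alone, median 0.59, adjusted p = 8.8e-05, but adjusted p = 0.822 with an estimated correlation). Ribosomal protein genes were enriched as well, 20 of 25 in wild type (21 adjusted over the list alone, median 0.52, or 0.30 at the lowest of 3 other scalings, adjusted p = 9.7e-05, but adjusted p = 0.66 with an estimated correlation). In the mutant 15 were up and 2 down (16 and 2 adjusted over the list alone, median 0.25, adjusted p = 0.0108, but adjusted p = 0.828 with an estimated correlation). Root markers were depleted, 12 down and 1 up of 13 in each genotype, as many adjusted over the list alone. Their medians were -1.68 in wild type (adjusted p = 0.0023, but adjusted p = 0.468 with an estimated correlation) and -1.74 in the mutant (adjusted p = 2.2e-05, but adjusted p = 0.239 with an estimated correlation).

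Autonomous-pathway genes were depleted on ribosomes, 6 of 7 in each genotype, as many adjusted over the list alone. Their medians were -0.82 in wild type (adjusted p = 8.8e-04, but adjusted p = 0.468 with an estimated correlation) and -0.52 in the mutant (adjusted p = 0.0108, but adjusted p = 0.35 with an estimated correlation). In the mutant the list of eIF3, eIF2 and TOR was depleted (2 up and 8 down of 16, as many adjusted over the list alone, median -0.23, adjusted p = 0.0182, but adjusted p = 0.374 with an estimated correlation). Phloem markers were enriched there (4 of 4, as many adjusted over the list alone, median 0.62, adjusted p = 0.0112, but adjusted p = 0.35 with an estimated correlation). Neither list passed for the interaction (adjusted p = 0.758 and 0.704). Both failed with limma at each pseudocount (0.0632 to 0.0699 and 0.0526 to 0.0531) and with quantile normalisation (0.127 and 0.053), and the first also without replicate 1 in all groups (0.0532). With the replicate block the sulfur list was enriched in both genotypes (adjusted p = 0.0025 and 0.01, but adjusted p = 0.498 and 0.441 with an estimated correlation). With the length correction the photosystem, ribosomal protein and autonomous lists did not pass in either genotype (adjusted p from 0.349 to 0.903), nor did eIF3 in the mutant (0.167). Other lists passed with it in wild type and mutant. They were upstream reading frames (2.2e-08 and 1.8e-06) and sulfur (0.0107 and 0.044) upward, and light harvesting (0.0237 and 0.0026) and guard cell markers (0.0047 and 0.044) downward. Phloem markers passed upward in wild type (9.0e-07), and light signalling and flowering repressors in the mutant (each 0.044). Sulfur also passed with no filter (0.0108 and 0.0199), library weights (0.0220 and 0.0452) and without any 1 replicate number, and in wild type with limma at each pseudocount. In wild type the list of eIF3, eIF2 and TOR passed downward with DESeq2 (0.0449) and without replicate 3 in all groups (0.0274) or ribosome-bound mutant 3 (0.0465). In the mutant cap-binding genes passed downward with DESeq2 (0.0139) and repressors upward with no filter (0.0387).

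In wild type 12935 genes differed between ribosome-bound and total mRNA, 6489 enriched and 6446 depleted, 2025 and 1634 by at least 2-fold. In the mutant 11186 did, 5570 and 5616, of which 960 and 1019 by at least 2-fold. With library size alone the median of all genes in wild type lay at -0.12. With the length correction 8214 genes passed there. Across genes length and enrichment had a Spearman's rho of -0.724 in wild type and -0.618 in the mutant.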

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

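The tests of a smooth length trend as the whole cause, of carry-over at the share the shortest genes need, of wild type RNA in the seedling sample, of root tissue share and of other splits for the correlation were chosen only after the result was seen. The genotype effect differed between ribosome-bound and total mRNA by the test of the interaction for 772 genes. By the same test it differed for the list of autonomous-pathway flowering genes (median log2 interaction 0.29) and for cytosolic ribosomal proteins (median -0.23), but for neither with an estimated correlation (adjusted p = 0.658 and adjusted p = 0.996 with an estimated correlation). The first did not pass with the length correction (median 0.02, adjusted p = 0.60) nor the second with quantile normalisation (median -0.05, adjusted p = 0.384). The interaction uses the total libraries with the opposite sign, so the rise of ribosomal protein genes in total mRNA enters their loss of association by construction.

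Short genes lost and long genes gained ribosome association in the mutant. Whether a length bias varied from library to library without regard to genotype could not be decided. The slopes of log2 ribosome-bound over total level on log2 length averaged -0.595 ± 0.0379 (SD, n = 3) in wild type and -0.388 ± 0.0605 in the mutant. They differed by 0.2066 with no overlap, but the exact permutation p was 0.1, the smallest possible, so such a bias could part the genotypes by chance. A smooth length trend as the whole cause is argued against by the 130 of 772 calls that still passed once it was removed, while over all 772 the median absolute log2 change fell from 0.56 to 0.33 and the median SE from 0.114 to 0.0946, and for the 642 whose call ended, picked by that outcome, from 0.53 to 0.26 and from 0.113 to 0.0938, so that these ended through a smaller change and not a larger error. Carry-over of unbound RNA at the 36.6% share the shortest genes need would have raised the median log2 ratio of 179 genes depleted on ribosomes by 1.306. That median went from -2.33 in wild type to -2.17 in the mutant, and the median change of these genes was 0.2494 (95% bootstrap interval 0.141 to 0.353). The bootstrap resampled genes and not libraries. A test of carry-over chosen beforehand could not decide, since this interval spans the smallest rise it asked for. A length bias between libraries, a smaller carry-over and a part from a smooth trend stay open, as does an effect of genotype on transcripts by length.

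EIF4E1 was higher in total mutant 2 than in the other total mutant libraries. It would need 43.7% of wild type RNA in that library, where 6 other genes, picked because they were nearly absent from the ribosome-bound mutant libraries, gave a median share of 2.782%. Of these, 3 differed by under 3-fold in total mRNA and say little (shares from -3198% to 11.6%), and the 3 with at least a 3-fold difference gave 0.574 to 3.10%. Wild type RNA in the seedling sample behind both mutant libraries of replicate 2 is argued against by the ribosome-bound library, where EIF4E1 gave a share of -2.129%. What raised EIF4E1 in that library stays open, and no biological explanation was tested.

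Root markers were lower in the mutant, in total mRNA and on ribosomes. A smaller share of root tissue cannot be told apart from a change in root cells or their transcripts, since markers that shoots also express would fall less and their expression by organ was not analysed here. On ribosomes the log2 changes of the 13 markers had a heterogeneity of 175.6 against a simulated 95% point of 20.9, with 1 up and 5 down, and in total mRNA of 109.9, with 0 up and 3 down. The marker that rose, SCR, did not pass with the length correction (adjusted p = 0.171) or without ribosome-bound wild type 1 or 2.

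With 3 against 3 samples there are 10 splits, too few for a share under 0.05. In each of the 5 contrasts 1 split, the real one, gave as many genes, and the others gave 0. The others mix the real groups, so a real difference adds to their spread and their 0 decides nothing. The real counts were 3254 (total), 5236 (ribosome-bound), 772 (interaction), 12935 and 11186 (ribosome-bound against total in wild type and mutant). Of the 10 splits 4 part all pairs of replicate numbers, the real one included, and the others 1 pair. The correlation of genotype changes between both kinds of library (0.692) was reached by 5 of the 10 splits, the highest other being 0.832.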

How the results depend on the processing

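The settings named as left-out replicates in all groups, DESeq2, library size alone, limma with a pseudocount of 1 and the length correction, with the block or without, were chosen after seeing the data. Of the values for single genes under other settings 6231 stayed on their side of the threshold, 777 no longer passed, 26 newly passed and 9 turned with a pass in either fit. Values that passed in neither fit count among the 6231 even where their sign turned. In data simulated at this depth edgeR recovered 50.7 and 46.3% of 1.5-fold changes in total and ribosome-bound mRNA and 16.4% for the interaction. The cause of a change with a setting was not tested unless stated.

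With the replicate block 6104 genes passed in total mRNA, 7914 on ribosomes and 1937 for the interaction, with 6 lists for the latter. On ribosomes EIF4B1 (adjusted p = 0.0372) and PAB2 (0.0370) passed with it. Among the list tests, and the genes with an adjusted p printed for that comparison, it changed no other call than those printed beside the results. A block for each genotype and replicate gave 4417 genes and 6 lists for the interaction. The block without replicate 2 gave 211 genes and 4 lists, and 0.72 for the mutant association of EIF4E1. The block with length correction gave 6533 genes and 15 lists in total mRNA and 391 genes and 4 lists for the interaction.

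In total mRNA 4955 genes passed with a pseudocount of 5 and 6184 with library weights. On ribosomes 2707 passed when only those libraries were fitted. For the interaction 479 passed with no filter, 350 with quantile normalisation, 1753 with library weights and 1352 with DESeq2. A fold minimum, which by construction removes smaller changes, left 186, 410 and 41 genes in these contrasts and 3659 and 1979 for ribosome-bound against total mRNA in wild type and mutant. The lists called for the interaction numbered 4 with a pseudocount of 0.1, with no filter and with library size alone, 1 with quantile normalisation and 5 with library weights. The correlation of 0.692 was 0.317 with no filter.

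Length correction left 3472 genes on ribosomes, 134 genes and 1 list for the interaction and 8214 genes for wild type association. It turned EIF4G to -0.17 on ribosomes and to 0.31 and 0.19 for association in wild type and mutant, with the block and without.

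Leaving out 1 library or 1 replicate number gave 473 to 3442 genes in total mRNA, 11 to 5368 on ribosomes, 0 to 1606 for the interaction and 10372 to 13079 and 8220 to 11290 for association in wild type and mutant. Single libraries alone gave 1662 to 3442, 3085 to 5368 and 159 to 1606 in the first of these. Lists called ranged from 2 to 5 for the interaction. EIF4E1 ranged from -2.30 to -1.33 in total mRNA and from -2.79 to -2.52 on ribosomes. Its mutant association, -0.06 with all libraries, was 0.64 without total mutant 2, 0.72 without replicate 2 and -0.41 without replicate 3.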

Other observations

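The test of neighbouring genes was chosen only after the result was seen, as were the genes CYP71A16, SCR and S6K2. Of 99 tested genes annotated as other non-coding RNA 2 rose and 40 fell on ribosomes (median -0.45), against 2 and 13 in total mRNA (median -0.17). Of 48 microRNA genes 0 rose and 6 fell on ribosomes (median -0.31) and 0 and 3 in total mRNA. Of 137 long non-coding RNA genes 4 rose and 12 fell on ribosomes. For the interaction 1 of the 99 rose and 5 fell. Small nucleolar RNA genes, 32 tested, had a median of -1.02 for ribosome-bound against total mRNA in wild type and -1.23 in the mutant. Libraries were poly(A)-selected, so these levels cover only such molecules as that step kept, and gene length was not taken into account.

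The marneral synthase gene MRN1 (-1.77 ± 0.30 in total mRNA, -1.85 ± 0.36 on ribosomes), CYP705A12 (-1.73 ± 0.34 and -1.99 ± 0.38) and CYP71A16 (-1.64 ± 0.32 and -1.66 ± 0.37) each fell. They are known as members of 1 gene cluster, were grouped after their values were seen and were not tested as a list. A hypothesis from this is that neighbouring genes changed together more often than chance. Of 11701 pairs of neighbouring tested genes 214 were called in the same direction in total mRNA, against a median of 178 and a 95% point of 199 over 10000 permutations of gene order (permutation p = 0.0032). On ribosomes there were 556 against a median of 443 (permutation p = 1e-04, the smallest they can give). Overlapping or near-identical neighbours that share reads could add such pairs and were not separated here. The permutations also took no account of gene length, which changes on ribosomes followed (Spearman's rho of 0.435), so neighbours of like length could add pairs too.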
